A study of Mus musculus with 4 samples.

How the data were processed

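Gene expression was measured on 4 arrays with RNA from the ventral midbrain of male mice, 2 from wild-type mice (WT) and 2 from mice without REV-ERBα, the nuclear receptor encoded by Nr1d1 (RKO). Per the labels' protocols, the mice were 10 to 15 weeks old on a C57BL/6J background, were entrained for more than 10 days to a light-dark cycle with 12 h of light, spent 2 days in constant darkness and were killed on the following day. The clock hour of collection is not given in the sources used here. Per the labels' protocols, total RNA was isolated with acid guanidinium thiocyanate, phenol and chloroform, and biotinylated cRNA was made from 1 µg of it. The labels call the replicates of each group biological. How many mice gave the RNA of an array is not given in the sources used here.

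The deposited table held 1 normalized intensity per probe set and array on a linear scale, for 35556 probe sets of an Affymetrix mouse gene array. GCOS and RMA are named in the submitters' processing notes, without versions and without the settings used. RMA as usually run subtracts background, makes the distribution of probe values alike on all arrays and summarises the probes of a probe set, so a shift common to most genes is removed from such values. The median intensity was 237 and 236 in the WT arrays and 240.1 and 236 in the RKO arrays, and values ran from 6.51 to 21034.5. Over the 13587 tested genes the median was 558.7 and 558.6 in WT and 539.8 and 558.6 in RKO, so RKO replicate 1 stood apart from the other arrays. It is also the array whose omission left the fewest changed genes; the cause was not tested. The scale was read from these values. Neither the direction nor the centring of the table needed a choice, since each column held 1 array's own intensities.

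The deposited intensities were transformed to log2 here, with no pseudocount, as the design fixed before the data were examined had allowed for linear values. Gene symbols came from the platform annotation. Of the probe sets, 21789 had 1 gene symbol, 1621 had several and 12146 were unnamed here. The last 2 kinds were left out of the gene test and tested apart, where 0 of 5490 unnamed probe sets and 0 of 915 with several symbols above the filter passed. All probe sets entered the filter's percentile and the correlations between arrays. Entrez identifiers of 21698 probe sets were matched to the RefSeq gene table of GRCm38.p6, and 0 symbols had to be updated. That table served only for gene names, for the order of genes along chromosomes and for whether Nr1d1 and Thra overlap, and its coordinates were not set against those of the array because the array annotation's build is not given in the sources used here. For each of the 19938 genes the probe set with the highest mean over the 4 arrays was taken. Genes whose mean lay below the 40th percentile of all probe sets (log2 7.38, an intensity of 167) were left out, which removed 6351 genes and left 13587.

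RKO was compared with WT by lmFit and eBayes of limma 3.58.1 in R 4.3.3, with 2 arrays per group and no covariate, and genes with a two-sided Benjamini-Hochberg adjusted p under 0.05 were called changed. Standard errors (SE) are limma's moderated ones. They rest on 2 residual degrees of freedom and 8.73 from the prior over all genes. An exact permutation test of 2 arrays against 2 cannot go below p = 0.333 for any single gene, so no such test was run per gene. The number of arrays limits the precision of every value. Nr1d1 was tested in a fit over all probe sets with 1 symbol, without the filter. Samples of a group were compared with each other first, and no pair of arrays shared more than 5 identical intensities.

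Gene lists were fixed before the data were examined. They covered ROR-element clock genes, E-box and D-box clock genes, other clock regulators, dopamine synthesis and transport, dopamine neuron transcription factors, dopamine breakdown, serotonin neurons, GABA neurons, glutamate neurons, astrocytes, oligodendrocytes, oligodendrocyte precursors, microglia, endothelium and pericytes, blood cells, choroid plexus and ependyma, hypothalamus and pituitary, neuropeptides, immediate early genes, heat shock and cold-inducible genes, glucocorticoid-responsive genes, metabolic genes bound by REV-ERBα in other tissues, inflammatory genes, the mitochondrial respiratory chain, and genes beside Nr1d1. Lists of leptomeninges, thalamus, noradrenaline neurons, dopamine neuron markers other than Th, caudal position genes and forebrain position genes were added after the first results had been seen. The leptomeninges and thalamus lists left out the 40 genes of lowest p, which had been looked at before. Each list with at least 3 tested members was tested with camera of limma at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over the fixed lists and, separately, over the added ones. Camera with an estimated correlation and fry, which asks whether the members of a list move one way on balance and does not compare them with other genes, were run beside it. Members of each list were also adjusted over the list alone.

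The genes named in the text follow a rule fixed before the data were examined. It took the 12 largest rises and the 12 largest falls among the changed genes whose RKO arrays did not overlap the WT arrays, Nr1d1, Th and Arntl in any case, and from each fixed list the members that passed or, where none did, up to 4 of lowest p. List members named as not passing beside members that passed, and those named as passing when adjusted over the list alone, fall outside this rule and were chosen after their values were seen, as were Ptpn3, Vav3 and the other members of the added lists.

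The same steps were tested on simulated data for RKO against WT over 13587 genes, of which 200 were given a known change. Of those changed by 0.3 on the log2 scale 62% were recovered, of those changed by 0.5 98%, and of those changed by 0.7 or by 1 100%. There were 10 false calls among the other genes. Noise was drawn for each gene and array on its own, with variances from limma's fitted prior. Deviations that genes of an array share were not simulated, so these rates need not hold for the real arrays. The alternatives tried were no filter and a 60th percentile filter on dim probe sets, a repeated quantile normalization, median centring, the mean of a gene's probe sets, each probe set on its own, an intensity trend and robust eBayes, other thresholds, a block for the replicate number, and leaving out each array in turn.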

Results

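Expression in the ventral midbrain, the part of the brain that holds the dopamine neurons of the substantia nigra and the ventral tegmental area, was compared between 2 RKO and 2 WT arrays. RKO mice lack REV-ERBα, a nuclear receptor of the circadian clock that represses its target genes, and the comparison asks which transcripts differ in this tissue without it. All tissue came from mice kept for 2 days in constant darkness. Pearson's r between arrays, over log2 intensities of all probe sets, was lowest between the WT arrays (0.99343), 0.993479 to 0.995176 between arrays of different groups and 0.995641 between the RKO arrays, so by this measure the WT arrays were no more alike than arrays of different groups. Over the 13587 tested genes the SD of the log2 difference was 0.0998 between the WT arrays and 0.0929 between the RKO arrays, against 0.109 to 0.143 between arrays of different groups.

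Nr1d1, the gene knocked out, was lower in both RKO arrays. Its intensity was 2897 and 3099 in WT and 1259 and 1229.7 in RKO, a fall of 2.41-fold (log2 difference -1.27, SE 0.0641, adjusted p = 0.00486). The array carried 1 probe set for Nr1d1. Which part of the gene was deleted is not given in the sources used here, so this value checks the labels only as far as the probe set lies in the deleted part or the remaining transcript is lost. Thra, which encodes the thyroid hormone receptor α and overlaps Nr1d1 on the opposite strand, also fell (log2 difference -0.57, SE 0.0583, adjusted p = 7.2e-04). Of the 15 tested genes in the list of genes beside Nr1d1, Thra and Igfbp4 (-0.28) fell, 13 did not pass and 0 rose. The list as a whole did not shift (median -0.02, camera adjusted p = 0.288), and 2 members passed when adjusted over the list alone. Thra passed under every setting in which it was tested, while Igfbp4 lost its call when any 1 of the 4 arrays was left out.

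Across the tested genes 87 were higher and 131 were lower in RKO, 218 in all or 1.60%. The largest rises were found in Ednrb, the endothelin receptor B (1.90-fold, log2 difference 0.93, SE 0.0607, adjusted p = 2.47e-05), Fabp7, a fatty acid-binding protein of astrocytes and radial glia (1.87-fold, 0.90, SE 0.0581, adjusted p = 2.39e-05), and Etnppl, which breaks down phosphoethanolamine (1.85-fold, 0.89, SE 0.0552, adjusted p = 1.98e-05). Rises of 1.46-fold to 1.83-fold followed in the membrane carbonic anhydrase Car14, the matrix protein Spon2, Plvap of fenestrated endothelium, Th, the BMP antagonist Chrdl1, the membrane-bound protease Mmp14, the tubulin Tuba8, the small GTPase Rasl11b and the co-chaperone Bag3. The deepest fall was that of Abhd12b, of the α/β hydrolase family, from intensities of 621 and 612 in WT to 125 and 146 in RKO (4.57-fold, log2 difference -2.19, SE 0.0725, adjusted p = 1.37e-07). Both RKO values lie below the filter's intensity of 167, so the size of this fall is uncertain and may be larger. Pmch, the precursor of melanin-concentrating hormone of the lateral hypothalamus, fell 2.20-fold (-1.14, SE 0.0648), and Ogn, a small leucine-rich proteoglycan of connective tissue, fell 2.16-fold (-1.11, SE 0.0664). The RKO intensities of Ogn, 153 and 137, were below 167 as well, so the same limit holds for its fold. Falls of 1.59-fold to 1.76-fold were measured for Stum, Islr, Itih2, Plxdc1, the cholesterol-esterifying enzyme Lcat, the protein kinase Prkch, the receptor partner Ramp3 and the sulfate transporter Slc13a4. The leptomeninges list added later left out the genes of lowest p, these genes and Ogn among them. That list therefore does not cover these falls. Whether less leptomeningeal tissue in the RKO samples accounts for any of them was not tested.

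Most changes were small. The median size among the 218 genes was 0.37 on the log2 scale, the smallest called difference was 0.26, 23 genes passed 1.5-fold and 4 passed 2-fold. At an unadjusted p under 0.05 there were 1739 genes, against 679 by chance. In all 218 changed genes the RKO arrays lay on 1 side of both WT arrays, which the call itself nearly requires. Over all tested genes the arrays were separated in this way for 41.8%, where chance gives 33.3%. The number of calls depended on the arrays kept and on the processing: without RKO replicate 1 there were 73 genes, 72 of them among the 218, without RKO replicate 2 there were 99, 87 of them shared, and with no filter on dim probe sets there were 31, 27 of them shared, while median centring gave 455 (191 higher and 264 lower), an intensity trend in eBayes 499 (190 and 309) and the arrays without WT replicate 2 gave 293 (142 and 151). Of the 24 genes with the largest rises and falls, 19 passed with no filter. Whichever array was left out, 12 of the 24 lay above 0, as with all 4 arrays. These genes were picked for their size in the same 4 arrays, which favours such an outcome.

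**Figure D1:**
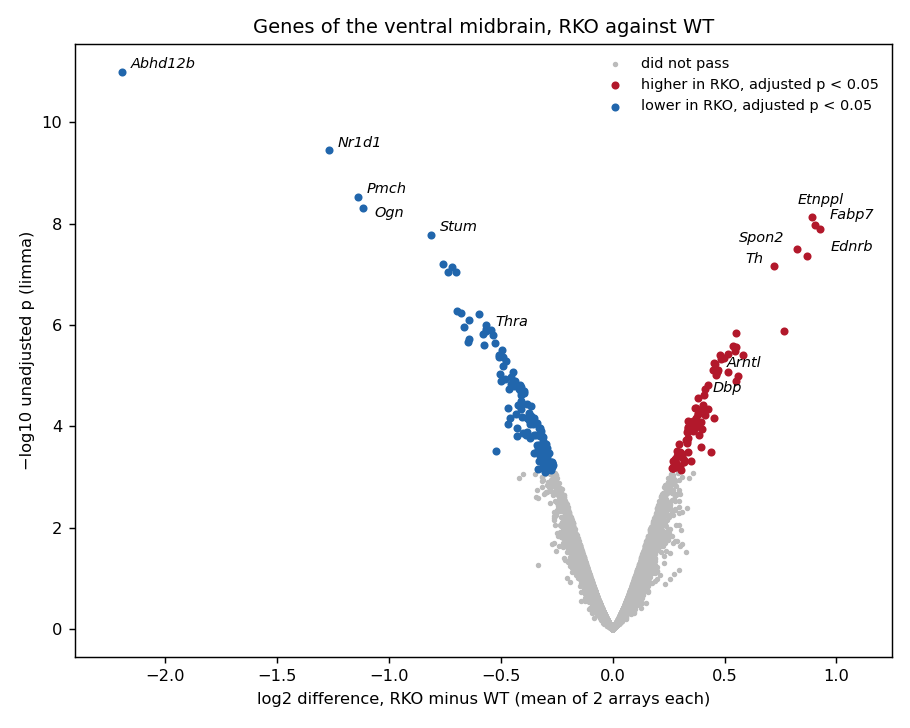
Log2 difference in expression (RKO minus WT, mean of 2 arrays each) against the negative log10 of limma's unadjusted p for the 13587 tested genes. Red points are the 87 genes higher and blue points the 131 genes lower in RKO at an adjusted p under 0.05, and Abhd12b and Nr1d1 lie farthest to the left at -2.19 and -1.27.

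Clock genes that REV-ERBα represses through ROR elements were higher in RKO. Arntl, which encodes the activator BMAL1, rose 1.39-fold (log2 difference 0.47, SE 0.0591, adjusted p = 0.00213), from intensities of 420.0 and 442 to 581 and 613. Nfil3, a repressor at D-boxes, rose by 0.47 and the repressor Cry1 by 0.33. Clock (0.07) and Gpam (0.03) did not pass. Of the 5 tested ROR-element clock genes 3 rose, also when adjusted over the list alone, and the list was higher as a whole (median 0.33, camera adjusted p = 3.95e-06; adjusted p = 0.30 with an estimated correlation).

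Genes driven through E-boxes and D-boxes, which BMAL1 and its partner CLOCK or the PAR-bZIP factors activate, were also higher. Of 14 tested, 4 rose, 0 fell and 10 did not pass. Those that rose were Dbp, a PAR-bZIP factor (0.41, SE 0.0578, adjusted p = 0.0044), Ciart, a repressor of CLOCK and BMAL1 (0.40, SE 0.0744), Tspan4 (0.30) and Per1 (0.27). When adjusted over the list alone 10 passed, all higher, among them Cry2 (0.25), Per3 (0.24), Nr1d2 (0.20), the paralogue of Nr1d1, and Per2 (0.18). The list median was 0.22 (camera adjusted p = 3.63e-11; adjusted p = 0.30 with an estimated correlation). Among 12 other clock regulators Rora, the activator that competes with REV-ERBα for ROR elements, fell (-0.36, SE 0.0589, adjusted p = 0.0109), 0 rose and 11 did not pass, with 1 lower when adjusted over the list alone. That list did not shift (median -0.03, camera adjusted p = 0.109). The calls for single clock genes depended on the filter and on the arrays kept: with no filter on dim probe sets limma called 0 of the 5 ROR-element genes (3 at an unadjusted p under 0.05) and 0 of the 14 E-box and D-box genes (10 at that p), and without RKO replicate 1 or RKO replicate 2 it called 0 of these 14 (10 and 9 at that p). Arntl and Nfil3 passed whichever array was left out, Cry1 only with all arrays or without WT replicate 2, and Rora not without RKO replicate 1. The clock hour of collection is not given in the sources used here, so it is also unknown whether all 4 arrays share it. The direction and size of the clock gene differences hold for the unknown time of collection alone. A difference in collection hour or clock phase between the groups cannot be told apart from them.

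Several genes of dopamine neurons rose, with Th at their head. Th encodes tyrosine hydroxylase, the rate-limiting enzyme of dopamine synthesis, and rose 1.65-fold (log2 difference 0.72, SE 0.0558, adjusted p = 7.45e-05), from intensities of 2168 and 2248 in WT to 3620.0 and 3664 in RKO. Rises of 0.29 to 0.42 were measured for Slc18a2, the vesicular monoamine transporter (0.42, SE 0.0573), Ddc, the decarboxylase that follows Th (0.34), Slc6a3, the dopamine transporter (0.33), the autoreceptor Drd2 (0.29), the nicotinic receptor subunits Chrnb3 (0.36) and Chrna6 (0.31), and the vesicular protein Slc10a4 (0.35). Of 14 tested genes of dopamine synthesis and transport, 8 rose, 0 fell and 6 did not pass, and 11 were higher when adjusted over the list alone. Spr (0.12), Pts (-0.01) and Qdpr (-0.04), which make or recycle the cofactor of Th, were among those that did not pass. The list median was 0.30 (camera adjusted p = 7.44e-16; adjusted p = 0.30 with an estimated correlation).

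Of 11 tested transcription factors of dopamine neurons, 0 passed at an adjusted p under 0.05 in limma (4 at an unadjusted p under 0.05), while En1 (0.27), En2 (0.25), Pitx3 (0.20) and Nr4a2 (0.18) were higher when adjusted over the list alone. The list was higher (median 0.05, camera adjusted p = 0.00637; adjusted p = 0.30 with an estimated correlation). Among 5 tested genes of dopamine breakdown Maob, a monoamine oxidase found mostly in glia and serotonin neurons, fell (-0.30, SE 0.0597, adjusted p = 0.031) and 4 did not pass, with 1 lower when adjusted over the list alone (list median -0.10, camera adjusted p = 0.0277; adjusted p = 0.414 with an estimated correlation). Beside these rises, markers of other tissue differed between the groups. A list of leptomeningeal genes, added after the first results were seen, was lower by a median of -0.30 (camera adjusted p = 1.72e-11; adjusted p = 0.0819 with an estimated correlation), and Pmch and Hcrt of the lateral hypothalamus were lower. Of 11 genes of caudal position, a list also added later, 0 passed and all lay above 0, with a median of 0.13 (camera adjusted p = 2.04e-06; adjusted p = 0.201 with an estimated correlation). Most of this list is dim: 9 more of its genes lay below the filter. Under the 60th percentile filter 3 were left, with a median of 0.07. Th passed under every setting in which it was tested, while 1 of the 14 genes passed with no filter and 1 without RKO replicate 2, Th in both, 3 without RKO replicate 1 and 5 without WT replicate 1. The call of Maob held without WT replicate 2 and was lost without any other array.

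**Figure D2:**
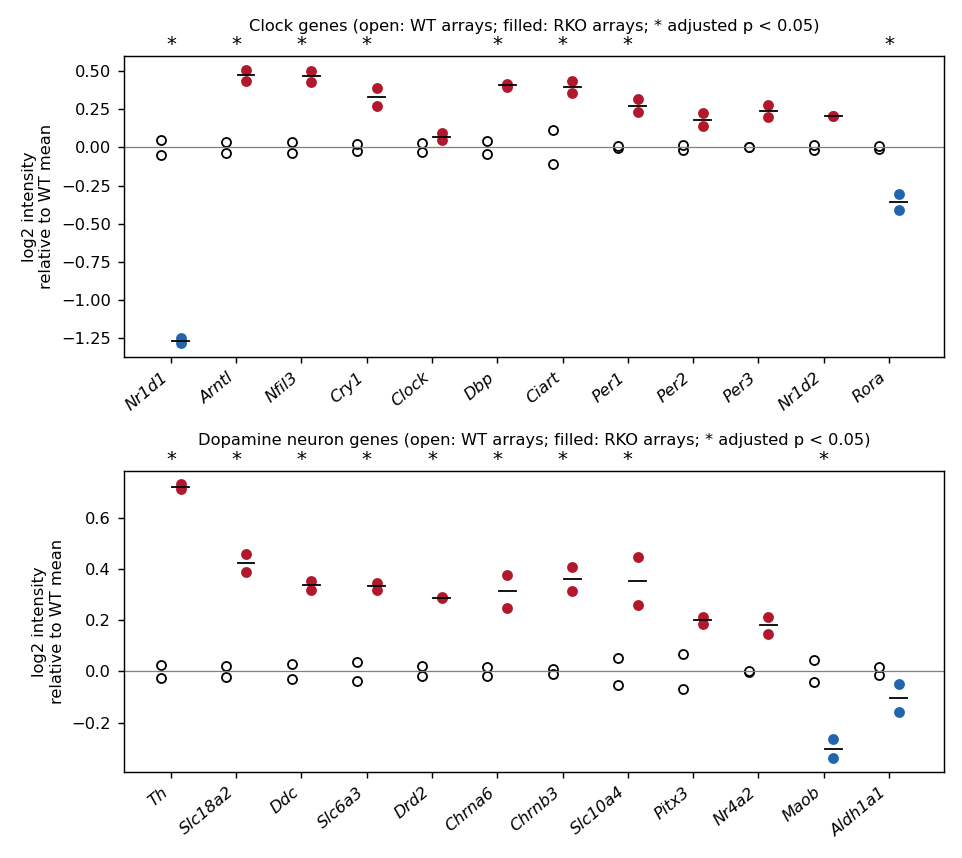
Log2 intensity of clock genes (top) and dopamine neuron genes (bottom) relative to the WT mean, with WT arrays as open circles, RKO arrays as filled circles (red above, blue below the WT mean) and a bar at the RKO mean of 2 arrays. Th stands at 0.72 and Arntl at 0.47 above WT, Nr1d1 at -1.27, and stars mark genes with an adjusted p under 0.05.

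In the serotonin list, of which 3 genes were tested, Gata3 rose (0.46, SE 0.0591, adjusted p = 0.00233), while Gata2 (0.29) and Htr1a (0.03) did not pass, and 2 were higher when adjusted over the list alone. Gata3 and Gata2 also specify GABA neurons of the midbrain, and the serotonin-specific Tph2 and Slc6a4 lay below the filter. The list median was 0.29 (camera adjusted p = 6.23e-04; adjusted p = 0.340 with an estimated correlation). Of 9 GABA neuron genes 0 passed in limma (1 at an unadjusted p under 0.05), with 1, Sox14 (0.28), passing when adjusted over the list alone and a list median of 0.07 (camera adjusted p = 0.0290; adjusted p = 0.350 with an estimated correlation). Of 8 glutamate neuron genes Slc17a7, the vesicular glutamate transporter of cortex and part of the thalamus, fell (-0.34, SE 0.0623, adjusted p = 0.0218) and 7 did not pass, with 2 lower when adjusted over the list alone. That list was lower by a median of -0.11 (camera adjusted p = 0.00266; adjusted p = 0.359 with an estimated correlation). With no filter Gata3 and Slc17a7 lost their calls, and Slc17a7 did so without WT replicate 2 or RKO replicate 1 as well.

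Cartpt, the precursor of the CART peptides, rose (0.50, SE 0.0589, adjusted p = 0.00143), while Tac1, the precursor of substance P (-0.35), and Npy (-0.33) fell. The other 8 of 11 tested neuropeptide genes did not pass, 2 were higher and 2 lower when adjusted over the list alone, and the list did not shift (median -0.09, camera adjusted p = 0.464). In the hypothalamus and pituitary list Pmch and Hcrt, the precursor of the orexins (-0.52, SE 0.0993, adjusted p = 0.0268), fell and 9 of 11 did not pass. Adjusted over the list alone 1 was higher and 2 were lower, and the list did not shift (median -0.02, camera adjusted p = 0.398). Among 11 glucocorticoid-responsive genes 3 rose, also when adjusted over the list alone: the kinase Sgk1 (0.48, SE 0.0556, adjusted p = 0.00136), the lipid droplet protein Plin4 (0.41) and Tsc22d3, also called GILZ (0.34). The widely used glucocorticoid target Fkbp5 stood at -0.02 and did not pass. The list median was 0.07 (camera adjusted p = 1.15e-04; adjusted p = 0.30 with an estimated correlation), and without RKO replicate 1 only Sgk1 passed. Of 14 immediate early genes 0 passed in limma (6 at an unadjusted p under 0.05), with 4 higher and 1 lower when adjusted over the list alone, among them Fos (0.25) and Egr1 (0.24). Their median was 0.12 (camera adjusted p = 7.46e-04; adjusted p = 0.30 with an estimated correlation). Cartpt was the 1 neuropeptide gene called without RKO replicate 1 or RKO replicate 2, Hcrt lost its call without RKO replicate 2, and with no filter Pmch alone of the genes in these lists kept its call.

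Among 13 astrocyte genes Gfap, an intermediate filament protein (-0.51, SE 0.0591, adjusted p = 0.00136), and Aldh1l1, a folate enzyme (-0.31, adjusted p = 0.0416), fell and 11 did not pass, with 2 higher and 3 lower when adjusted over the list alone. The median of that list was 0.00081 and its mean -0.05, and it did not shift in 1 direction as a whole (camera adjusted p = 0.464). Its members went both ways: 7 of the 13 lay above 0, and 6 of the 13 had an unadjusted p under 0.05. Of 13 oligodendrocyte genes Opalin fell (-0.30, SE 0.0642, adjusted p = 0.0446) and 12 did not pass, with 2 lower when adjusted over the list alone. All 13 lay below 0, with a median of -0.11 (camera adjusted p = 6.55e-05; adjusted p = 0.359 with an estimated correlation). Oligodendrocyte precursor genes, of which 0 of 9 passed in limma (3 at an unadjusted p under 0.05), had a median of -0.09 (camera adjusted p = 0.0111; adjusted p = 0.414 with an estimated correlation), and 1, Bmp4 (-0.26), was lower when adjusted over the list alone. Of 12 endothelial and pericyte genes 0 passed (4 at that unadjusted p), with 1 higher, Cldn5 (0.19), and 3 lower, among them Vtn (-0.23), when adjusted over the list alone. Their median was -0.10 (camera adjusted p = 0.0111; adjusted p = 0.359 with an estimated correlation). The 10 choroid plexus and ependyma genes all lay above 0 with a median of 0.10 and 0 passing (2 at that unadjusted p), 2 of them higher when adjusted over the list alone, Sostdc1 (0.26) and Otx1 (0.18) (camera adjusted p = 5.07e-04; adjusted p = 0.30 with an estimated correlation). Microglia genes did not shift (13 tested, 0 passing in limma, 2 at that unadjusted p, 0 when adjusted over the list alone, median -0.07, camera adjusted p = 0.230). Of the blood cell list 2 genes were tested, too few for a list test, and Alas2 (0.10) and Slc4a1 (0.12) did not pass over all genes or when adjusted over the list alone. With no filter Gfap, Aldh1l1 and Opalin lost their calls, Aldh1l1 did so without WT replicate 1 or RKO replicate 1, and Opalin without any array but WT replicate 2.

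The remaining fixed lists did not shift. Of 9 metabolic genes bound by REV-ERBα in other tissues Fabp7 rose and 8 did not pass, and the same single gene passed when adjusted over the list alone. Their median was -0.01 and their mean 0.10 (camera adjusted p = 0.109). Nos2, the inducible nitric oxide synthase, rose (0.31, SE 0.0611, adjusted p = 0.0311) near the lower limit of intensity, from 147 and 159 to 193 and 185, and the other 7 of 8 inflammatory genes did not pass, with 1 higher and 1 lower when adjusted over the list alone (median -0.02, camera adjusted p = 0.961). The call of Nos2 held without WT replicate 2 and was lost without each other array. Of 23 respiratory chain genes 0 passed in limma and 0 had an unadjusted p under 0.05, their median was -0.00303 (camera adjusted p = 0.637), and 0 passed when adjusted over the list alone. The same held for 11 heat shock and cold-inducible genes, such as Hsph1 (-0.13) and Hsp90aa1 (-0.06), of which 0 had an unadjusted p under 0.05 and 0 passed by either adjustment (median -0.01, camera adjusted p = 0.925). In the tissue lists added after the first results were seen, 10 of 18 leptomeningeal genes fell, 0 rose and 8 did not pass, with 13 lower when adjusted over the list alone (camera adjusted p = 1.72e-11; adjusted p = 0.0819 with an estimated correlation). Of 19 thalamus genes 2 fell, Ptpn3 (-0.44) and Vav3 (-0.32), 0 rose and 17 did not pass, with 1 higher and 7 lower when adjusted over the list alone (median -0.07, camera adjusted p = 2.18e-04; adjusted p = 0.177 with an estimated correlation). Vav3 lost its call without any array but WT replicate 2, and with no filter both did.

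**Figure D3:**
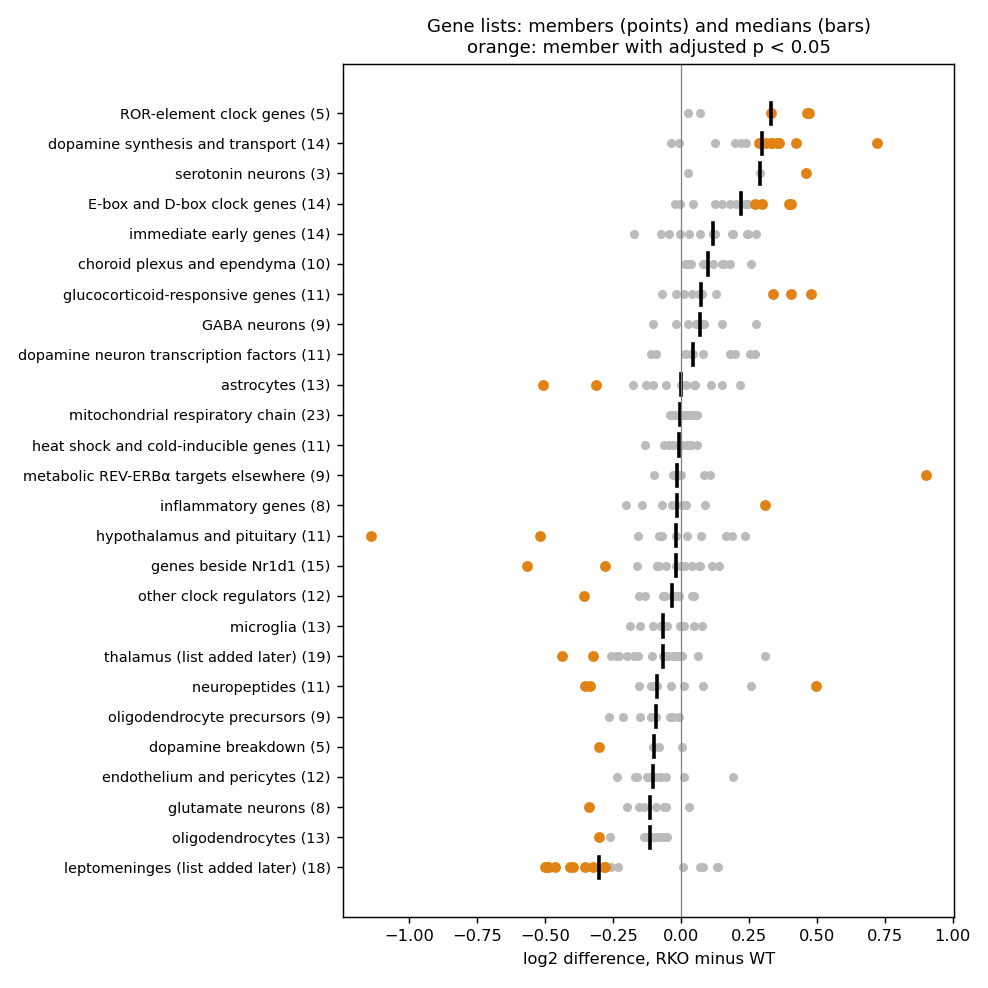
Log2 difference (RKO minus WT) of each tested member (points) and the median (bar) of gene lists. Shown are the fixed lists with at least 3 tested members and, of the added lists, leptomeninges and thalamus. The number of tested members is in brackets, and members with an adjusted p under 0.05 are in orange. Medians run from 0.33 for the ROR-element clock genes to -0.30 for the leptomeninges list.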

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

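The crossed pairing of replicate numbers was the setting chosen after the data had been seen; all other settings were chosen before. Gene counts are given as total, higher and lower in RKO. The main setting called 218, 87 and 131. With no filter on dim probe sets there were 31, 8 and 23 (27 genes shared with the 218), with median centring 455, 191 and 264, with an intensity trend 499, 190 and 309, at an adjusted p under 0.1 382, 158 and 224, and at an unadjusted p under 0.01 with at least 1.5-fold 23, 7 and 16. Leaving out 1 array, with its lone partner assumed to vary like the other group, gave 73 to 293 genes, 32 to 142 higher and 41 to 151 lower, lowest without RKO replicate 1. A 60th percentile filter called 296 genes, 138 of them among the 218. A second quantile normalization called 166 (165 shared), and the mean of a gene's probe sets 224 (216 shared). Each probe set on its own gave 187 probe sets, and robust eBayes gave 218 genes (218 shared). These counts stayed within 1.5 times the main count, which does not make the genes the same. With no filter 19938 genes were tested in place of 13587, and limma's variance prior was fitted to them as well; the cause of this fall and of the other shifts was not tested. Of the 54 named genes other than Nr1d1 that passed, 64 of 216 values lost the call when an array was left out and 0 turned sign. Among named genes 35 lost the call with no filter and 9 with the second quantile normalization. Nr1d1 kept its call throughout, with log2 differences from -1.32 to -1.22. Of the fixed gene lists 14 were called, 11 to 17 in the settings with the preset correlation, 0 with an estimated correlation and 1 with fry, the dopamine neuron transcription factors. Of the added lists fry called the leptomeninges and the dopamine neuron markers other than Th (adjusted p = 0.0174 each) and the thalamus (0.0335), and not the caudal and forebrain position genes (0.0889 each). The ROR-element list, the E-box and D-box list and the dopamine synthesis and transport list each had adjusted p = 0.30 with an estimated correlation and 0.0601, 0.0533 and 0.0601 with fry, against 2.96e-08 to 0.00152, 3.09e-16 to 1.02e-07 and 3.76e-29 to 1.03e-10 over the settings with the preset correlation. The inflammatory list, higher by camera's direction and not called, was lower with adjusted p = 0.0431 under the 60th percentile filter, which tests fewer of its genes. With the replicate number as a block (replicate block) 259 genes were called, 105 higher and 154 lower, all 218 included; the deviations of same-numbered arrays correlated at -0.114 and no label ties the numbers to a shared animal or day. Pairing the numbers crosswise gave 696, 334 and 362. Leaving out probe sets with names for shared transcripts was not run, since the array has none so named, nor was robust eBayes for the lists, since camera has no such option. Genes below an intensity of 167, such as Tph2, Slc6a4 and all noradrenaline neuron markers, were tested only with no filter, where 0 of 6 noradrenaline neuron genes were called (0 at an unadjusted p under 0.05, median 0.10) and 0 of 6 serotonin neuron genes (3 at that p, median 0.20).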

Other observations

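The tests on the collagen genes and on the neighbours of Nr1d1 were chosen only after the result was seen, all lists used in the tests but the hypothalamus list were added after the first results, and the reading of 4 tests was changed after their values were known, as said at each.

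Several changed genes outside the fixed lists were picked after their values were seen. Rln3, the precursor of relaxin-3, made in the nucleus incertus of the hindbrain and in a few midbrain cells, rose 1.40-fold (intensities 1068 and 1060.0 in WT, 1446 and 1529 in RKO). Dio2, the deiodinase that makes active thyroid hormone in glia, rose 1.46-fold, and Apln, the precursor of the peptide apelin, rose 1.38-fold. The GABA-A receptor subunits Gabra4 and Gabrd fell by 0.52 and by 0.39 on the log2 scale, and the protein kinase Prkcd fell by 0.57. The thalamus list left out the genes of lowest p, so it could hold neither Gabra4 nor Prkcd. Whether less thalamic tissue in the RKO samples accounts for the falls of Gabra4, Gabrd, Prkcd or Rora was not tested. Of genes that interferons induce, Ifitm3 fell by 0.44, Rtp4 by 0.41, Ifit1 by 0.38 and Ifitm2 by 0.32, with no list of such genes tested.

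Genes of the leptomeninges, the thin membranes over the brain, were among the falls. In the list written after the 40 genes of lowest p had been seen, and without those genes, the falls were in Aldh1a2, the enzyme of retinoic acid synthesis (-0.50), Serping1 (-0.49), the GABA transporter Slc6a13 (-0.49), the organic anion transporters Slc22a8 (-0.46) and Slc22a6 (-0.28), the proteoglycans Dcn (-0.41) and Bgn (-0.35), Slc47a1 (-0.40), Foxc1 (-0.32) and Aebp1 (-0.28). Without RKO replicate 1, 4 members of the list passed, without RKO replicate 2, 5 did, and with no filter 1 did, Ranbp3l, which the filter otherwise removes. The brightest gene of the list, Ptgds, stood at 6951 and 6496 in WT and 5605 and 5648 in RKO and did not pass. Noradrenaline neuron genes had 0 members above the filter, 11 caudal position genes, of which 0 passed, had a median of 0.13 (camera adjusted p = 2.04e-06; adjusted p = 0.201 with an estimated correlation), 2 of them higher when adjusted over the list alone, and 19 forebrain position genes had a median of 0.03 (camera adjusted p = 0.164) and 0 that passed. Under the 60th percentile filter 3 caudal position genes were left, with a median of 0.07. Of 18 dopamine neuron markers other than Th 7 rose, and 14 were higher when adjusted over the list alone (camera adjusted p = 2.69e-16; adjusted p = 0.0819 with an estimated correlation). The same genes were called in the fixed dopamine lists above, so this gives no separate support for a rise of these markers. Of these markers 4 passed without WT replicate 1, 2 without RKO replicate 1, 0 without RKO replicate 2 and 0 with no filter.

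Th rose more than the other dopamine neuron genes. More dopamine neurons in the RKO tissue would raise the other 18 markers too, by the outcome written beforehand to above 0.5 of the rise of Th. The median of the 18 was 0.247 (0.201 to 0.271 in the 4 pairs of an RKO and a WT array). It lay below 0.5 of the rise of Th in every pair (0.344 to 0.378), and all 18 lay below Th in all 4 pairs. Th stood above their median by a mean of 0.487 over the 4 pairs (0.483 to 0.493). This met the outcome written beforehand against more dopamine neurons. The bound took no account of background or of expression in other cells, which can lessen a marker's rise. Of the 18 markers, 14 lie above an intensity of 334, and the 4 pairs share the same arrays. For these 18 markers the values argue against a larger share of dopamine neurons as the reason for all of the rise of Th. Such a larger share may still account for part of it. Tissue cut further towards the hindbrain could raise the other markers: the caudal genes stood above the forebrain genes by 0.103 (0.0782 to 0.134 in the 4 pairs), which is the outcome written beforehand for this explanation, but the forebrain genes were not lower, a condition added after the values were seen, so this stays open. More noradrenaline neurons, which also make Th, stay open too, as 0 of their markers passed the filter and the median of 0.0986 over 6 of them with no filter comes from dim genes, and so does an effect of the genotype on Th itself, which no test here addresses.

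Many genes of the leptomeninges, 2 of 19 genes of the thalamus list, and Pmch and Hcrt of the lateral hypothalamus were lower in RKO, which less of such tissue in the RKO samples could bring about. Of the 23 genes in the leptomeninges list, 0 belong to another list and 18 passed the filter. The median of these 18 was -0.302 (-0.325 to -0.283 in the 4 pairs), on the side this explanation needs. Against it, the 4 collagens Col1a1, Col1a2, Col3a1 and Col6a1, abundant in meningeal fibroblasts, had a median of 0.0748 (0.011 to 0.146), but 2 of these 4 lie above an intensity of 334, too few to exclude it by a rule set afterwards that asks for 3. For the thalamus the median was -0.0660 (-0.0911 to -0.0527), which by the bound of -0.1 written beforehand would exclude less thalamic tissue; that bound was set aside after the value was known, since the list leaves out the 40 genes of lowest p and the bound took no account of the level these genes have in the midbrain itself. Camera found the list lower at its preset correlation (adjusted p = 2.18e-04) and not with an estimated one (adjusted p = 0.177), so less thalamic tissue is neither shown nor excluded. The 10 hypothalamic and pituitary genes other than Pmch had a median of 0.00254 (-0.0462 to 0.0633 in the 4 pairs), above that bound in every pair, and with 10 genes past the filter this met the outcome written beforehand against less hypothalamic tissue. It was set aside after the value was known: the list leaves out Pmch, which fell most, its members go both ways (Hcrt at -0.52, Oxt at 0.24, 5 of 10 at or above 0), and 2 of them lie above an intensity of 334, so less tissue of the lateral hypothalamus alone stays open. For all of these genes a change in expression without a change in tissue was not tested.

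Some changed genes lie near Nr1d1 on its chromosome, where a stretch of the donor strain's chromosome kept around the targeted allele might alter expression or probe binding. Of the 199 tested neighbours, 100 genes on each side without Thra, 6 had changed (3.02%), against 210 of 13378 other genes (1.57%), an odds ratio of 1.95 (95% interval 0.699 to 4.39, one-sided Fisher's exact p = 0.0984). The 6 were Plxdc1, Coa3, Hcrt, Xylt2, Igfbp4 and Gpr179, of which Gpr179 rose and the others fell. This is too few to tell a kept stretch from none, and a loss of REV-ERBα as the reason for these changes was not tested.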
